A study of Sus scrofa with 14 samples.

How the data were processed

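RNA from the meniscus, the fibrocartilage pad of the knee, was measured on 14 arrays, 1 per animal, from male Wuzhishan pigs. In 7 animals the tissue was taken 24 weeks after surgery on the anterior cruciate ligament (the osteoarthritis group, OA), and in 7 animals 24 weeks after a sham operation. Each array was treated as a separate animal because the series description gives 14 pigs divided at random between the groups. Per the labels' protocols, total RNA was extracted with TRIzol, amplified and labelled with Cy3, so each array has a single colour.

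The deposited scanner files hold spot intensity values. Per the file headers, they were made with Agilent Feature Extraction 11.0.1.1, which subtracted the background and removed spatial trends within each array; the deposited intensity values were not normalized between arrays. Each array had 45220 spots, of which 1417 were control spots, and 43603 distinct non-control probes. The authors' series table holds log2 values; scale, centring and direction were worked out by setting each column against the same array's scanner signal. Its columns followed that signal with a Spearman rho across probes of 0.994 to 1.00, shared their quantiles, and had medians of 5.99 on each of the 14 arrays. The deposited log2 values were therefore taken as quantile-normalized, not centred by gene and running in the direction of the signal; how they were made is not given in the sources used here. That table was used only as an alternative.

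Values were computed as log2 of the processed signal minus the array's 75th percentile over non-control probes. Spots marked by the scanner software as non-uniform or as population outliers were set missing (82 in all), no spot was saturated, and spots of one probe were averaged, which concerned 50 probes. Probes well above background on at least 7 of the 14 arrays were tested, whatever the group, which kept 38818 and left out 4785. The groups were compared, OA minus sham, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Intervals quoted for a log2 change are 95% intervals from the same fit.

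Gene names came from matching the RefSeq accession in the scanner files, without its version, to the RefSeq gene table of the Sscrofa11.1 assembly. Of the 43603 probes, 5779 carried a RefSeq accession and 5461 of these matched, giving 2389 genes. The other probes carried Ensembl transcripts (7535), TC identifiers (13875) or other identifiers (16414) and stayed without a gene name, so a gene not named here was not analysed here. No coordinates are given because the genome build behind the array design is not given in the sources used here. The design fixed in advance took gene names from a column of the scanner files; these names replace it. Where a gene had several probes, the probe with the highest mean signal over the 14 arrays stood for it. In all 2258 genes were tested, 1211 of them with more than 1 probe. Disagreement between probes is stated for some genes only, so silence on the other probes does not mean that they agreed.

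Signals are given as the geometric mean of the processed signal over the 14 arrays, in arbitrary units. A probe not well above background on any array of a group has only a bound there: the mean of the brighter group was set against the mean, over the dimmer group's arrays, of the higher of the probe's own value and the lowest value among probes well above background on that array. No fold is given where that bound came to less than 1. The number of arrays limits the precision.

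Before the data were examined, 36 gene lists were fixed for the tissue's matrix, pathways of joint degeneration and markers of other cell types that a dissected meniscus can hold. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. These tests and the principal components used values with marked spots kept, since they take no missing values. The rule for named genes was also fixed then: up to 12 genes with the largest increases and up to 12 with the largest decreases past the threshold with a sign that held when each array was left out; from each list, up to 4 members past the threshold with the smallest p, or the 2 smallest where fewer than 2 passed; and 20 osteoarthritis genes whatever their result. Some genes this rule selects are not reported here. Array measures were compared with two-sided exact permutation tests over all 3432 assignments, adjusted over 4 measures.

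Alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50 followed by the 75th percentile, no filter, a filter on all 14 arrays, marked spots kept, the authors' table, array weights, trended and robust variances, the replicate number as a block, slide or scan day as a random block, each array left out, and, for genes, the mean of all probes. The normexp alternative used median signals, as the scanner files held no mean signal. Arrays sharing a scan time were taken as 1 slide, and scan days were numbered in the order of the arrays, not of the calendar; the day numbered 2, that of OA 1, came last. With a random block, or trended variances, lists were tested with camera on the moderated statistics. Alternatives added after seeing the data left out whole slides, used the array's brightness as a covariate, or repeated camera at an estimated correlation for lists that passed under another alternative.

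The fit was tested on simulated data with the real means and spreads of the 38818 probes. For OA against sham it recovered 37 of 100 probes changed by 2-fold and 88 of 100 changed by 4-fold, with the right sign, and called 5 of 38618 unchanged probes. The list test, over 2258 genes, called the 1 shifted list and 0 of 28 others. Each simulated value was drawn independently, without correlation between genes or differences between slides. These counts therefore do not give the rate of false calls on the real arrays.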

Results

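Meniscus expression was compared between 7 pigs examined 24 weeks after anterior cruciate ligament surgery, and 7 pigs examined 24 weeks after a sham operation. The series title gives degenerative meniscus tissue in knee osteoarthritis as its subject, and the comparison asks which transcripts differ between operated and sham knees. Expression was read on single-colour arrays, and 38818 probes, among them those of 2258 named genes, were bright enough to be tested.

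On the OA arrays 67 named genes were called higher and 6 lower than on the sham arrays. No slide or scan day held both groups, so these calls cannot be told apart from a difference between slides. With the slide as a random block 1 gene stayed higher and 0 lower. Genes said below to rise or fall did so in this comparison of arrays. The 5 largest increases were in GCNT7, a glycosyltransferase gene of the N-acetylglucosaminyltransferase family, the uncharacterised locus LOC100156694, SOCS2, a feedback inhibitor of cytokine and growth hormone signalling, MYOD1, a transcription factor of muscle commitment, and LYPD1, a modulator of nicotinic acetylcholine receptors. GCNT7 was higher by 1.66 ± 0.19 on the log2 scale (SE, n = 7 per group; limma adjusted p = 0.00098), a 3.16-fold difference that all 7 OA arrays shared when set against the sham mean. LOC100156694 was 2.98-fold higher (limma adjusted p = 0.011), SOCS2 2.79-fold (adjusted p = 0.011), MYOD1 2.71-fold (adjusted p = 0.0070) and LYPD1 2.55-fold (adjusted p = 0.014), each in 7 of 7 OA arrays. Of the 6 decreases, 1 was in a gene well above background on every array: IFNGR2, a chain of the interferon gamma receptor, fell by 0.72 ± 0.16 on the log2 scale in 7 of 7 OA arrays (adjusted p = 0.019).

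Among the next increases, FASN, the fatty acid synthase, was higher by 1.24 ± 0.26 (SE; log2, adjusted p = 0.017) and was the brightest of the 12 genes with the largest increases, with a mean signal of 10586. SLC52A2, a riboflavin transporter, was higher by 1.18 ± 0.29 at a signal of 4095. SCG5, a chaperone of a prohormone convertase, rose by 1.33 ± 0.23. CYP17A1, an enzyme of steroid hormone synthesis, rose by 1.26 ± 0.26 and TMPRSS15, the intestinal protease enteropeptidase, by 1.17 ± 0.23. KLF1, a transcription factor of red cell precursors, rose by 1.18 ± 0.32. Several of these genes gave a dim signal: MYOD1 averaged 14.7, CYP17A1 19.9, GCNT7 26.2 and KLF1 41.3, against a median of 86.6 over all tested probes.

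The other 5 decreases were in dim genes, 4 of them at the background in OA. PPYR1, a receptor of pancreatic polypeptide, was lower in OA (adjusted p = 0.022) but well above background on 1 of 7 OA arrays, so that its fitted change of -1.36 ± 0.30 rests on values at the background and its size is not known. PNLIP, pancreatic lipase, fell by 1.13 ± 0.30 and was above background on 6 of 7 OA arrays. CLDN17, a tight junction claudin, the uncharacterised LOC100155663 and ODAM, a protein of enamel-forming and junctional epithelium, were well above background on all 7 sham arrays and not well above background on any OA array. ODAM was at least 1.05-fold lower in OA (adjusted p = 0.014), and no fold can be given for CLDN17 (adjusted p = 0.014) or LOC100155663 (adjusted p = 0.040). With normexp background correction these 5 values turned positive, whereas that of IFNGR2 stayed negative.

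**Figure D1:**
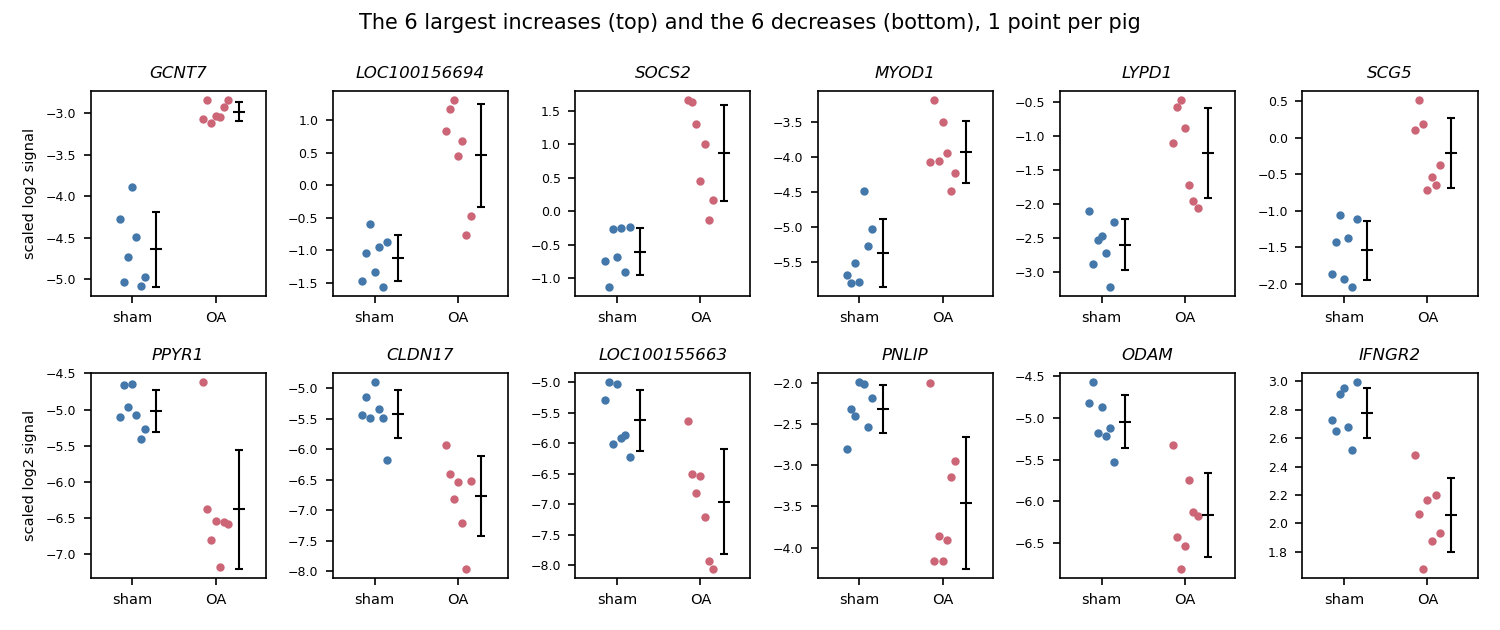
Scaled log2 signal (log2 processed signal minus the array's 75th percentile) of the 6 genes with the largest increases and the 6 with decreases; each point is 1 pig (blue, sham; red, OA), and the bar beside it shows the mean and SD of 7 arrays. The 7 OA points of GCNT7 lie above all 7 sham points.

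Different probes of a gene often disagreed. For SOCS2, SCG5 and LEP the other tested probe went the other way (log2 changes of -0.61, -0.57 and -0.34, none past the threshold), and for FASN the other 2 probes gave -0.08 and -0.56. The 3 probes of SLC52A2 had one sign, at 1.18, 0.30 and 0.05. Of the 73 called genes, 38 had more than 1 probe; of their 66 other probes, 29 had the sign of the call and 37 the opposite sign. GCNT7, MYOD1, LYPD1, CYP17A1, KLF1 and TMPRSS15 were read by 1 probe each.

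Counted over all probes, 1449 of 38818 passed the threshold, 1120 higher and 329 lower in OA, and 7593 had an unadjusted p under 0.05. Only 125 of the 1449 belonged to a named gene. The fitted change was at least 2-fold for 705 of these probes and for 28 genes, 23 higher and 5 lower; for 4 of these 5 lower genes the size rests on OA values at the background. Probes called lower were dim: 304 of the 329 lay below the median signal of 86.6, with a median of 11.96 against 65.4 for those called higher. The median change of all tested probes was -0.05, and over 10 equal bins of signal it went from -0.36 in the dimmest to 0.09 in the brightest. The split of higher against lower calls depended on scaling, with 1385 and 784 after median scaling and 1509 and 747 in the authors' table. With normexp background correction it was 17635 and 778. It also depended on the filter: requiring all arrays gave 1122 higher and 69 lower, and a median change of 0.02. The main filter let in probes well above background on the sham arrays alone, as for CLDN17, LOC100155663 and ODAM. The arrays used mattered too. Lower calls were the more numerous without OA 1 (1307 higher, 1403 lower). The same held without slide 5 (1181 higher, 1374 lower), an alternative chosen after seeing the data.

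**Figure D2:**
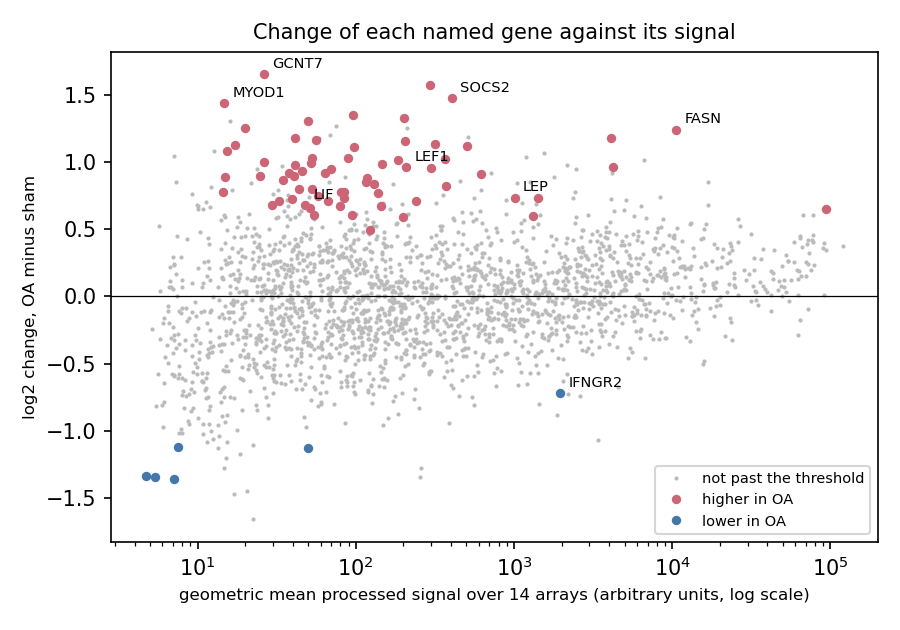
Log2 change (OA minus sham) of the 2258 tested genes against their mean processed signal in arbitrary units on a log axis; red points are the 67 genes higher in OA, blue points the 6 lower, and grey points genes not past the threshold. IFNGR2 is the bright gene among the decreases, at a signal of 1965.

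The arrays of the groups differed in brightness, and no slide or scan day held both groups. The raw 75th percentile was 539 ± 82.6 in sham and 274 ± 125 in OA (SD, n = 7; exact permutation p = 0.0035, adjusted p = 0.0070). The share of probes well above background was 91.2% ± 1.8 in sham and 78.1% ± 8.9 in OA (SD, n = 7; exact permutation p = 0.00058, adjusted p = 0.0023). The sham arrays lay on slides 1 and 2, scanned on day 1; OA 1 lay on slide 3, scanned on day 2, and OA 2 to OA 5 (slide 4) and OA 6 and OA 7 (slide 5) were scanned on day 3 (numbered by array order; day 2 came last). The raw 75th percentile of OA 6 and OA 7 was 404 and 492, within or near the sham range of 418 to 622, and that of OA 1 to OA 5 was 156 to 250. Brightness thus differed between slides within OA. The exact permutation tests, here and for the control spots below, took single arrays as exchangeable, so their p does not allow for slides. Principal component 1, with 29.1% of the variance, differed in mean between the groups (exact permutation adjusted p = 0.037), but OA 1, OA 6 and OA 7 lay within the sham range, and OA 2 to OA 5, the arrays of slide 4, lay apart at 38.9 to 99.6. The adjusted p rose above 0.05 without any one of sham 2, sham 3, sham 4 or OA 2 to OA 5, with 0.071 as the highest; component 2 did not (adjusted p = 0.21).

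**Figure D3:**
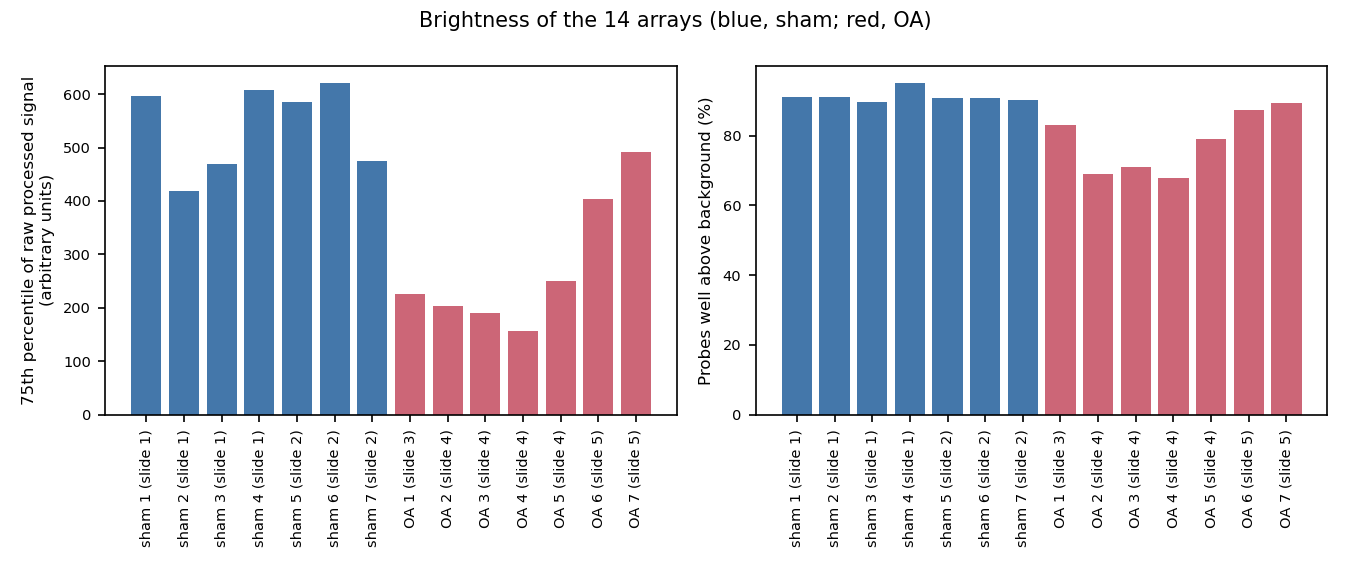
Raw 75th percentile of the processed signal in arbitrary units (left) and percentage of probes well above background (right) for each array, by slide; blue bars are sham and red bars OA. OA 2 to OA 5, on slide 4, lie between 67.9% and 78.9%, below every sham array.

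The gene calls depended on these slides. With the slide as a random block (estimated correlation 0.225) 18 probes passed, all higher in OA, and GCNT7 was the 1 gene left (limma adjusted p = 0.025; over its 32 alternatives the adjusted p ran from 0.00011 to 0.063). That fit assumed a single correlation for all probes, and each slide lay within 1 group. It therefore cannot show that GCNT7 is free of a slide effect of its own, and the same limit holds for the scan day. With the scan day as a random block 148 probes and 7 genes passed, and with array brightness as a covariate, chosen after seeing the data, 4 probes and 0 genes. Without slides 3 and 4, also chosen after seeing the data, 195 probes and 6 genes passed, of which 4 genes were among the 73; All 1120 higher and 329 lower probes kept their sign there on arrays that had also taken part in the call, with median changes of 0.82 (0.94 with all arrays) and -0.82 (-1.20 with all arrays). GCNT7 then stood at 1.76 (limma adjusted p = 0.041). LEP stood at 0.91, LEF1 at 0.89, LIF at 0.83 and IFNGR2 at -0.71, none past the threshold there (limma adjusted p from 0.11 to 0.19). LOC100155663 was lower there too, but it was not well above background on any OA array, so its size is not known. KLF1 stood at 1.07, SCG5 and CYP17A1 at 1.03 and MYOD1 at 1.01. FASN stood at 0.79, SOCS2 at 0.63, LYPD1 at 0.59, TMPRSS15 at 0.58, LOC100156694 at 0.50 and SLC52A2 at 0.30. From KLF1 to SLC52A2, none of these passed there (limma adjusted p from 0.17 to 0.78). The count of probes moved by over 1.5 times without sham 1 (730), sham 2 (909), sham 3 (932), sham 6 (827), OA 1 (2710), OA 2 (796), OA 3 (732) or OA 5 (951). The 67 higher genes became 36 without sham 1, 40 without sham 6, 44 without OA 2 and 39 without OA 3, and the 6 lower genes became 46 without OA 1, 3 without OA 3 and 15 without OA 6. Of the genes with the largest increases, the 6 decreases and the 5 list members past the threshold, KLF1 passed in 2 of the 14 fits that left out 1 array, LOC100155663, PNLIP and TNNI1 in 3, SLC52A2 in 7 and PPYR1 in 13; the others of this set passed in all 14.

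None of the 29 gene lists that could be tested passed the threshold as a group, by camera at either correlation or by fry; 1 list had an unadjusted camera p under 0.05 and 1 an unadjusted fry p under 0.05. The lists held 5 genes past the threshold, each of them higher in OA and each alone in its list. With the slide as a random block none of these 5 passed (limma adjusted p from 0.12 to 0.21). Adjusted over the list alone, 10 genes in 9 lists passed.

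Of 23 measured inflammatory cytokines and nuclear factor kappa B targets, 1 rose: LIF, a cytokine of the interleukin-6 family, by 0.68 ± 0.14 (SE; log2, limma adjusted p = 0.014), in 7 of 7 OA arrays at a signal of 48.1. IL1A stood at 0.39 ± 0.15 (adjusted p = 0.16). IL6 itself stood at 1.26 ± 0.50 with a 95% interval of 0.21 to 2.31 (adjusted p = 0.17) and all 3 of its probes positive; over its 32 alternatives the adjusted p ran from 0.012 to 0.93 and passed in 2. IL1B, TNF and PTGS2, the inducible cyclooxygenase, stood at 0.31 ± 0.39, -0.15 ± 0.23 and 0.46 ± 0.53. Adjusted over the list alone, the count was also 1, and camera gave an adjusted p of 0.97.

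None of the matrix genes passed. Of the 4 measured cartilage matrix and chondrocyte identity genes, ACAN, the core protein of aggrecan, stood at 0.24 ± 0.37 (SE; log2), SOX9, the master transcription factor of chondrocytes, at -0.43 ± 0.46, and C15H2orf82 at -0.54 ± 0.75; with 4 genes the list was not tested. Among 5 fibrous matrix genes COL5A1, a chain of type V collagen, stood at 0.68 ± 0.24 (limma adjusted p = 0.12) and SPARC at 0.25 ± 0.25. Only 1 of the 3 probes of COL5A1 and 2 of the 7 of SPARC were positive. DCN, decorin, the only small leucine-rich proteoglycan measured, was near equal at 0.01 ± 0.21 and a signal of 90681. Of 7 hypertrophy and mineralization genes, DMP1 and MEF2C had the smallest p, at 0.48 ± 0.20 and 0.46 ± 0.24, and COL10A1, a collagen of hypertrophic cartilage, stood at 0.28 ± 0.20. HAS1 and HAS3, hyaluronan synthases and the 2 measured glycosaminoglycan synthesis genes, stood at 0.92 ± 0.78 and 0.16 ± 0.25.

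Of 12 matrix-degrading proteases 0 passed, and camera gave an adjusted p of 0.97. PLAU, urokinase, stood at 0.72 ± 0.36 and ADAMTS1 at 0.95 ± 0.52 (SE, log2). Positive values were given by 1 of the 2 probes of PLAU and 2 of the 2 of ADAMTS1. The collagenase MMP1 stood at 0.06 ± 0.78 and the stromelysin MMP3 at -0.14 ± 0.47, and the 95% interval of MMP1 ran from -1.59 to 1.72. Of 6 protease inhibitors 0 passed; CST3, cystatin C, stood at -0.30 ± 0.18, TIMP2 at -0.42 ± 0.29 and TIMP1 at -0.13 ± 0.21. Of the 20 osteoarthritis genes fixed in advance, 11 carried a name here, and 0 of these passed over all probes or adjusted over the list alone; VEGFA stood at -0.80 ± 0.62. The other 9, among them COL2A1, COMP, PRG4 and MMP13, were not analysed here.

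Of 5 measured genes of Wnt signalling 1 rose: LEF1, a transcription factor that acts with beta-catenin, by 0.96 ± 0.18 (SE; log2, adjusted p = 0.0098), although its other 2 probes stood at 0.02 and -1.26. WNT2B stood at 0.40 ± 0.29, and the list gave an adjusted camera p of 0.87. Of 9 cholesterol and lipid synthesis genes FASN alone rose, while ACACA, acetyl-CoA carboxylase, stood at -0.33 ± 0.18, and the list's median was -0.04 with a mean of 0.18. Among 12 adipocyte markers LEP, leptin, rose by 0.74 ± 0.16 (SE; log2, limma adjusted p = 0.021) at a signal of 1011, and DGAT2 stood at 0.58 ± 0.23. The list's median was 0.23, and camera gave an adjusted p of 0.87. Without slides 3 and 4, an alternative chosen after seeing the data, the adipocyte list gave an adjusted camera p of 0.020 at the preset correlation and 0.94 at an estimated one; with all arrays the estimated correlation gave 0.98.

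Markers of other tissues were read beside these. Of 16 skeletal muscle genes TNNI1, the slow troponin I, rose by 0.71 ± 0.18 (adjusted p = 0.041), MYH7, slow myosin heavy chain, stood at 0.97 ± 0.29 (adjusted p = 0.075), and the median was -0.08. Adjusted over the list alone, 2 of the 16 passed. Of 9 neutrophil and mast cell markers S100A12 stood at 1.27 ± 0.37 (adjusted p = 0.065), passing when adjusted over the list alone, and S100A9 at 0.76 ± 0.29 (adjusted p = 0.15). None of 10 macrophage, 13 T and NK cell, 5 endothelial, 5 pericyte and smooth muscle or 6 synovial lining genes passed: CD14 stood at -0.45 ± 0.24, LYZ at 0.89 ± 0.68, IL7R at 0.56 ± 0.21, CD3D at -0.39 ± 0.33, PECAM1 at -0.89 ± 0.42, CDH5 at 0.49 ± 0.31, ACTA2 at -0.31 ± 0.24, MYLK at 0.34 ± 0.28, CLU at -1.07 ± 0.60 and CLIC5 at 0.21 ± 0.15. The B and plasma cell gene CD79A stood at 0.40 ± 0.34, and HBE1, the 1 erythrocyte gene, at 0.15 ± 0.20. Of 6 osteoclast genes ITGB3, an integrin subunit, stood at 0.61 ± 0.17 (adjusted p = 0.055; past the threshold over the list alone) and CTSK at -0.31 ± 0.20, and of 5 Schwann cell genes SOX10 stood at 0.34 ± 0.22.

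**Figure D4:**
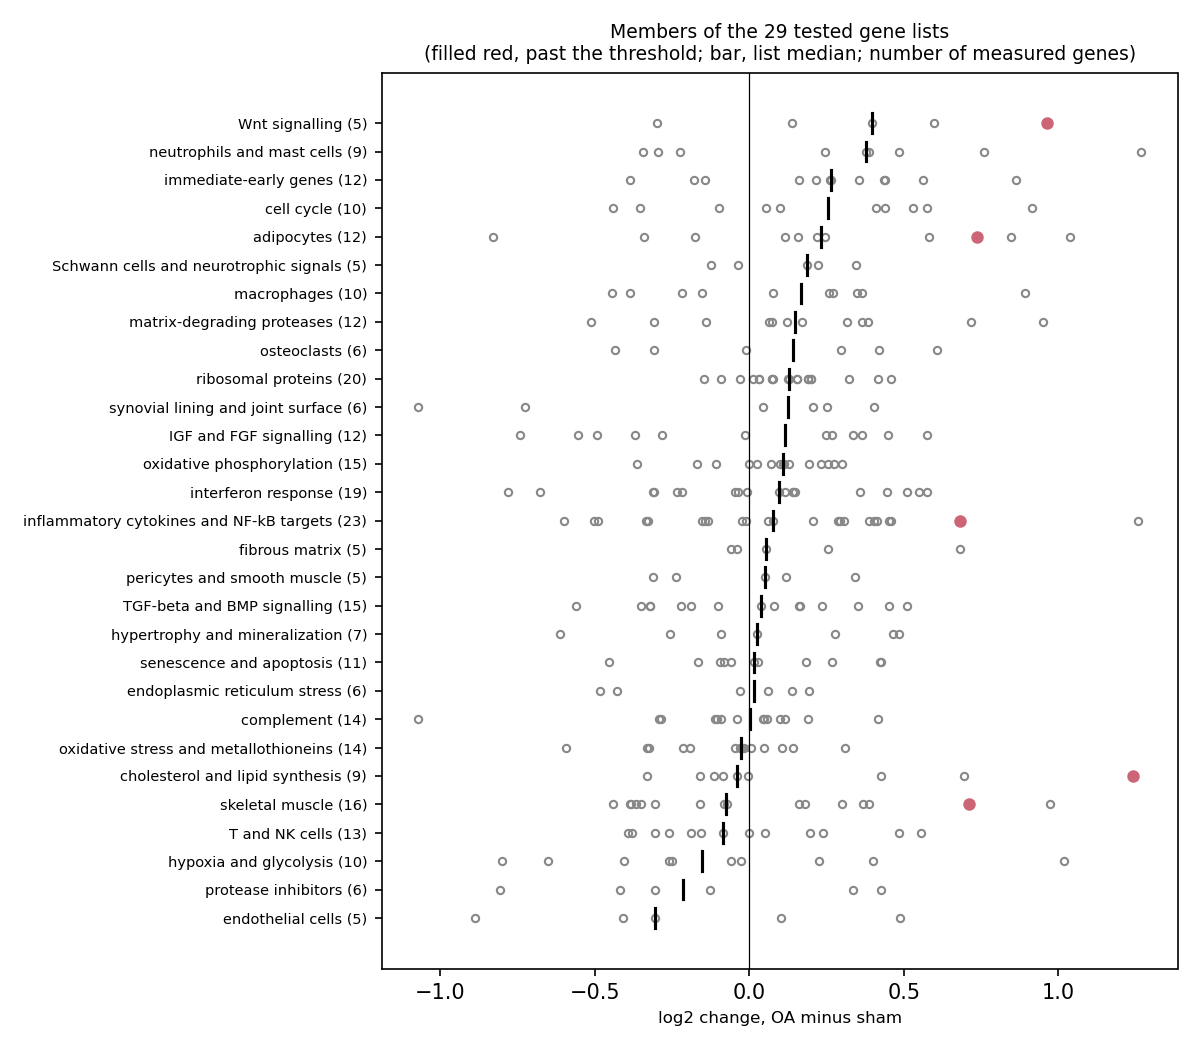
Log2 change (OA minus sham) of every measured gene of the 29 tested lists, 1 point per gene, with the number of measured genes after the list's name; filled red points are genes past the threshold and black bars list medians. The 5 red points are LEF1, LEP, LIF, FASN and TNNI1.

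In the remaining lists 0 genes passed over all probes. Among 10 cell cycle genes HMGB2, a chromatin protein, stood at 0.92 ± 0.26 (SE; log2, adjusted p = 0.058, past the threshold over the list alone), with all 4 of its probes positive, and AURKB at -0.44 ± 0.24. Among 10 hypoxia and glycolysis genes TPI1, triosephosphate isomerase, stood at 1.02 ± 0.30 (adjusted p = 0.073, past the threshold over the list alone), with its other 4 probes negative, and HIF1A at -0.41 ± 0.29. Of 20 ribosomal protein genes 17 had a positive change with a median of 0.13, RPS20 at 0.46 ± 0.15 and RPS12 at 0.42 ± 0.16; the list's camera p of 0.050 became 0.87 after adjustment (adjusted p = 0.98 with an estimated correlation). Without slide 4, also chosen after seeing the data, the ribosomal list gave an adjusted camera p of 0.016 in the same direction (0.99 at an estimated correlation), and with normexp background correction its direction was reversed. Of 15 oxidative phosphorylation genes SDHD and COX6A1 stood at -0.37 ± 0.20 and 0.28 ± 0.18. The 15 genes of transforming growth factor and BMP signalling were represented by BMP6 at -0.32 ± 0.20 and BMP7 at 0.51 ± 0.33, and the 12 of IGF and FGF signalling by IGF2 at -0.74 ± 0.40 and IGFBP6 at 0.45 ± 0.24.

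The stress and regulatory lists gave the smallest p for genes on both sides of 0. In the interferon response list of 19 genes ZBP1 stood at -0.31 ± 0.31 and MX2 at 0.58 ± 0.59, and among 14 complement genes C8G stood at -0.29 ± 0.23 (SE; log2). Among 6 endoplasmic reticulum stress genes ATF4 stood at -0.48 ± 0.25 and CALR at -0.43 ± 0.29, and among 14 genes of oxidative stress and metallothioneins MT3 stood at -0.59 ± 0.33 and KEAP1 at -0.33 ± 0.19. GADD45A and IGFBP7, of 11 senescence and apoptosis genes, stood at 0.42 ± 0.25 and 0.27 ± 0.19. FOXO3 and BECN1, the 2 measured autophagy and FOXO genes, stood at -0.23 ± 0.25 and -0.14 ± 0.22. Of 12 immediate-early genes KLF6 and NR4A3 stood at 0.44 ± 0.28 and 0.86 ± 0.60, and ARNTL, the 1 measured clock gene, at -0.32 ± 0.26.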

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

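The tests on probes called lower, described last here, were chosen after the result was seen. A single array stood far from the other 6 of its group in 11 of the 198 groups of values examined, where chance gives about 5%; sham 4 was that array in 3 of them and no array in more. Sham 4 had 95.2% of probes well above background against at most 91.1% on the other sham arrays (gap over range 0.756). It was also highest for CD14 (0.644) and lowest for IGFBP7 (0.595). Sham 3 was lowest for IL1A (0.580) and highest for TNNI1 (0.638), and sham 2 was highest for ACACA (0.612). Among the OA arrays, OA 1 was highest for PPYR1 (0.683), OA 3 was highest for DMP1 (0.667) and lowest for CD3D (0.597), OA 2 was lowest for C8G (0.607), and OA 7 was lowest for ACAN (0.597), with 5.86 against 7.45 or more on the other OA arrays.

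The 153 negative control spots, which no comparison above uses and which match no transcript, were higher in OA after scaling by 1.38 on the log2 scale (exact permutation p = 0.00058, adjusted p = 0.0012), while the 320 E1A spike-in spots differed by 0.08 (p = 0.53, exact permutation). The scaling subtracts each array's 75th percentile, which was lower in OA (raw mean 274 against 539). How much of the 1.38 is a raised floor is therefore not known. By itself a raised floor would make dim probes higher, but the dimmest bin as a whole had a median change of -0.36. The control value thus does not settle the source of the 329 probes, most of them dim, called lower in OA. Requiring all arrays to be well above background left 69 lower calls. The control value runs the way of the 1120 probes called higher, of which 646 lay below the median signal. Whether it contributes to those calls was not tested. Of 252 probes called lower in OA 1 to OA 5 against sham 1 to sham 4, 34.9% were lower in OA 6 and OA 7 against sham 5 to sham 7, arrays not used for the call. Their median there was 0.22, inside the 0.19 to 0.36 of uncalled probes of matched signal, as dim arrays on slides 3 and 4 would give. Without those slides all 329 probes stayed negative, with a median of -0.82 (-1.20 with all arrays). Uncalled probes of matched signal had 0.06 to 0.16 there. In that fit 39 probes were called lower. Of its 195 calls in either direction 72 were shared with the calls on all arrays, so the 39 need not be among the 329. LOC100155663 and PPYR1 were lower there too. They were well above background on 0 and 1 of the OA arrays, so the sizes are not known. The remaining arrays had taken part in the call, which favours a kept sign, so the values without slides 3 and 4 are not an independent check. They therefore do not offset the result on the arrays not used for the call, where most lower calls did not repeat. Dim arrays as the source of the lower calls stay open beside a lower level in the animals.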

How the results depend on the processing

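Leaving out whole slides and the brightness covariate were chosen after seeing the data; the cause was not tested for any shift below, beyond what the construction of an alternative shows. Against 1449 probes past the threshold, quantile normalization gave 2242, the authors' values 2256, no filter 2551, normexp 18413 (which also moved the median change of all probes from -0.05 to 0.34), the slide as a random block 18 and the scan day 148. Leaving out slides 3 and 4 gave 195, slide 4 alone 236, slide 5 2555, slide 1 26 and slide 2 642, and the brightness covariate 4; single arrays left out gave 730 to 2710. Against 67 genes higher, normexp gave 730, the slide block 1, the day block 7, the mean of all probes 36, leaving out slides 3 and 4 3, slide 4 3, slide 1 2, slide 2 28, the brightness covariate 0, and single arrays left out 36 to 73. Against 6 genes lower, quantile normalization gave 15, median scaling 20, normexp 51, the filter on all arrays 1, the authors' values 24, array weights 17, the slide block 0, the day block 0, leaving out slides 3 and 4 3, slide 4 0, slide 5 37, slide 1 0, slide 2 2, the brightness covariate 0, and single arrays left out 3 to 46. Against 28 genes at 2-fold or more, normexp gave 13, no filter 47, the slide block 1, the day block 6, leaving out slides 3 and 4 6, slide 4 3, slide 5 64, slide 1 2, the brightness covariate 0, and single arrays left out 18 to 51. Against 0 lists, normexp gave 4, leaving out slides 3 and 4 2, slide 4 1 and the brightness covariate 2; at an estimated correlation, also run after seeing the data, none of these passed (lowest adjusted p 0.27). Principal component 1 was oriented with OA higher, and its scores were not recomputed without an array. That it kept its direction (62.6 to 85.0 between groups) without any single array therefore says little about its stability. The component missed the threshold without 7 of the arrays (values of 62.6 to 72.7). Brightness and detection kept both direction and threshold. Of the 1449 probes, quantile normalization kept 1368, median scaling 1412 and the filter on all arrays 1023. Values for named genes changed sign in 76 further cases over the alternatives, with neither value past the threshold. Where 1 of the values had passed, signs turned under normexp alone: PPYR1 0.63, CLDN17 0.67, LOC100155663 0.68, PNLIP 0.0176, ODAM 0.62, C8G 0.48, CD3D 0.69, BMP6 0.55 and ACACA 0.55, and the oxidative phosphorylation and ribosomal lists at adjusted camera p 0.040 each; it adds a constant before the dim arrays are scaled. Signal over background limits the dim genes, since 8 of the 73 called genes were not well above it on at least 1 array.

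Replicate numbers 1 to 7 occur in both groups. No pairing by number was visible in the values: 2 of the 7 same-numbered pairs had deviations correlated above 0.1, and 0 of the sham arrays matched its own number best. Same-numbered arrays lay on different slides, so these values cannot exclude a pairing in the experiment. With the number as a replicate block 335 probes passed, with 20 genes higher, 2 lower and 16 at 2-fold or more, and 0 lists.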

Other observations

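The genes in this paragraph were chosen after their values were seen. In 3 called genes a second probe also passed in the same direction: C7H6orf15 (0.84 and 1.72), BMP15 (0.66 and 0.86) and MUC13 (0.65 and 1.01, with 2 more probes at 0.07 and -0.56). The 2 passing MUC13 probes had signals of 93156 and 14.4, so whether they read the same transcript is not known. In AGPAT1, called higher at 0.75 (limma adjusted p = 0.041), the other probe passed in the opposite direction at -1.13 (adjusted p = 0.012).

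The tests in this paragraph and the next, other than the count of splits, were chosen after the results they concern were seen. Of 100 splits of the 14 arrays into 7 and 7, drawn with the real one included, 1 gave as many probes past the threshold as the real split, the real one itself (1449, highest other 1), and the same held for genes higher (67, highest other 0), genes lower (6, highest other 0) and genes at 2-fold (28, highest other 0), which speaks against a chance assignment for these counts but not for the surgery as their source, since the slides follow the groups. For lists the real count was 0, so all 100 gave at least as many by construction, and nothing follows about the real grouping. The other splits gave up to 11 lists, so camera at the preset correlation also called lists for arbitrary groupings of these arrays. With all arrays more probes were called higher than lower, but not without OA 1 (1307 higher, 1403 lower) or slide 5 (1181 higher, 1374 lower). Dimmer OA arrays are a possible explanation of the higher calls, and it stays open. The 531 probes called higher in OA 1 to OA 5 against sham 1 to sham 4 had a median change of 1.53 there and of 0.49 in the brighter OA 6 and OA 7 against sham 5 to sham 7, above the 0.12 to 0.23 of uncalled probes of matched signal. But OA 6 and OA 7 were still dimmer than these sham arrays, by a log2 difference of -0.32 against -1.35 in the arrays used for the call, and with brightness as a covariate 3 higher probes were left. Without slides 3 and 4, on arrays that had taken part in the call, the 1120 higher probes had a median of 0.82 (0.94 with all arrays). A difference between slides or scan days cannot be told apart from the surgery, because each holds 1 group; with the slide as a random block 18 probes were left.

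The probes of one gene shared little of the change between OA and sham. Across 1211 genes with more than 1 probe, the change of the brightest probe correlated with the mean of the others at r = 0.24 (genes are not independent replicates), below all 99 other splits of the same arrays, which ran from 0.38 to 0.76. Error of dim probes as the cause is argued against by 329 genes with every probe above a signal of 1000, where r was 0.53 and again below all 99 others (0.62 to 0.93); over all genes, slide 2 against slide 1 within sham gave 0.62, and slide 4 against slides 3 and 5 within OA gave 0.42. The median of the other splits was 0.61, so the sham contrast lay near it and the OA contrast near the lowest split. Over the 329 brighter genes the sham and OA contrasts gave 0.79 and 0.67, against a median of 0.84. Low agreement between probes thus also occurred between slides within OA, where the surgery did not differ. A difference between array batches that acts on single probes cannot be told apart from the surgery, since batches follow the groups and the r of 0.24 is the observation itself. Transcript forms that differ after surgery were not tested and stay open.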
